A study of Mus musculus with 2 samples.

How the data were processed

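MicroRNA sequencing of total RNA from the hippocampus of male B6CASTF1/J mice aged 14 days was analysed from 2 count tables, one per biological replicate. Each label names 3 males by number and marks the samples as separate biological replicates. Both labels carry the same donor identifier and neither says how the tissue was pooled, so SDs and the coefficient of variation measure the spread between these samples, which may be in part technical. The labels give a size range of under 30 for the libraries. The tables as deposited hold raw counts of reads per annotated miRNA gene, not normalized, on mm10 with the GENCODE M21 annotation, per the accompanying text. The aligner, the counting tool, adapter trimming and read filters are not given in the sources used here. The deposited tables have no header line. Each has 3 count columns, for either strand, the strand of the gene and the opposite strand, and the column on the gene's strand was taken from the totals as the larger of the stranded columns. A further 4 rows of each count reads that were given to no gene and stayed out of library sizes and tests.

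Those rows held 41.3% unmapped, 26.3% multimapping and 4.85% reads outside miRNA genes in replicate 1, and 20.7%, 37.5% and 6.51% in replicate 2. Reads ambiguous between genes were 0 in the stranded column, and 1.58% and 2.11% in the column that ignored strand. The assigned counts were 3793934 in replicate 1 and 2554997 in replicate 2, so that 1 count was worth 0.264 and 0.391 CPM. By counting error alone, a gene with 0 counts could have been at up to 0.791 or 1.17 CPM, from 3 counts of the total. This limit does not hold for genes whose reads map to several places, since multimapping reads were given to no gene. Shares of a single library carry 95% Wilson intervals for counting error only.

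All 2202 gene identifiers matched the annotation, from which symbols, positions, host genes and hairpin sequences were taken. Symbols of the lists that the annotation names otherwise were matched through RefSeq synonyms, by which Mir7j and Mir7k are let-7j and let-7k. Mir496b, which was listed for the Dlk1-Dio3 domain, was dropped because it does not lie on chromosome 12. A host gene had to lie on the same strand, and a miRNA gene was called exonic or intronic from the host's transcripts. Hairpins were searched for stretches of 20 nucleotides shared, in either orientation, with another miRNA gene that does not overlap them. Genes with such a stretch are reported as uncertain.

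CPM were computed as counts on the gene's strand per 1000000 counts assigned to miRNA genes, and log values as log2(CPM + 0.5). A gene was called detected at 2 CPM or more in each library. Genes were compared between the libraries with a two-sided exact binomial test given the library totals, with Benjamini-Hochberg adjustment over genes with at least 10 counts in sum and a threshold of 0.05. The test covers counting error only. The spread between replicates was estimated with edgeR 4.0.16 (common dispersion, intercept-only design, TMM factors 0.997 and 1.003) in R 4.3.3, since edgeR's quasi-likelihood test cannot contrast 2 libraries without replication. Its interval came from 100 resamplings of the genes. DESeq2 1.42.0 gave alternative size factors and dispersions. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

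The text names the 20 genes with the highest mean CPM and, of each list, the 3 detected members with the highest mean CPM. It also names the 5 genes in each direction with the largest log2 ratio between the libraries, among those with a mean of 10 CPM or more that passed the exact binomial test. This rule, the lists, the tests of the main comparisons and most alternatives were set before the data were examined. Fisher's exact test of detection and most tests of explanations were chosen afterwards. The lists are neuron-enriched, oligodendrocyte, astrocyte and glia-enriched, myeloid and microglia, endothelial and mural, erythroid, choroid plexus and ciliated epithelium, miR-200 epithelial family, sensory cluster, posterior Hox, muscle and heart, liver and pancreas, skin and pluripotent cell. Lists by family or locus are let-7, the miR-99, miR-100 and miR-125 list, miR-30, miR-181, miR-26, miR-17/92 and its paralogues, Dlk1-Dio3 domain, Sfmbt2 cluster, other imprinted and activity-regulated. Mir132 and Mir212 stand in both the neuron-enriched and activity-regulated lists, and Mir134 in both the activity-regulated and Dlk1-Dio3 lists.

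The median log2(CPM + 0.5) of each list of at least 3 members with a count was set against that of all other genes with a count, by a two-sided permutation test of 100000 resamples, adjusted over 23 lists. A list's median log2 ratio of the libraries was placed among 10000 random lists of the same size matched on mean CPM. Alternatives were other detection minimums, pseudocounts, count filters, scalings, stretch lengths and denominators, the column that ignored strand, and each library alone.

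The exact binomial test and the dispersion were tested on simulated data made from the gene means and library sizes of this comparison. For the exact test, counts were drawn with counting error only, as the test assumes, and without further spread between replicates. The rates of calls therefore do not hold for libraries that differ beyond counting error, as these do. With no gene changed, 0 of 498 tested genes were called. With 200 genes changed and 497 tested, the test called 39.6% of the genes changed by 1.2-fold, 53.1% at 1.5-fold, 78.7% at 2-fold and 97.9% at 4-fold. In the same simulation 51.6% of unchanged genes were called with library totals and 1.31% with TMM-scaled totals, because changes in abundant genes shift the shares of the others. A planted coefficient of variation of 0.4 was recovered as 0.388 over 498 genes. Counts on the opposite strand and multimapping reads were left out of the comparisons and are given as shares.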

Results

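MicroRNA sequencing was carried out on hippocampus of male mice aged 14 days. The mice were B6CASTF1/J, the first-generation cross of C57BL/6J and CAST/EiJ. The series held 1 group with 2 biological replicates, and the label of each named 3 males by different numbers. Both labels also carry the same donor identifier, so the spread between the samples may be in part technical. Small RNA reads were counted on 2202 annotated miRNA genes, each standing for a hairpin precursor, so that the arms of a hairpin were not separated. Replicate 1 had 3793934 counts on miRNA genes from 13791106 reads, and replicate 2 had 2554997 counts from 7239133 reads. Levels are given as counts per 1000000 counts on miRNA genes (CPM), as mean ± SD of the 2 libraries (n = 2). With no second condition, the comparisons were of genes and gene groups within the tissue and of the 2 libraries with each other.

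The first comparison asked which miRNA genes made up the hippocampal profile. Mirlet7b, a let-7 gene of a family that rises as cells differentiate, was highest at 87109 ± 12463 CPM (SD, n = 2). It was followed by Mir127 of the imprinted Dlk1-Dio3 domain at 80675 ± 6391 CPM, Mir99a at 74586 ± 15074 CPM and Mir139, which lies in an intron of Pde2a, at 71768 ± 6147 CPM. Mirlet7i stood at 54567 ± 8830 CPM, Mir770 at 39616 ± 24042 CPM and Mirlet7g at 38031 ± 8846 CPM. The 10 most abundant genes, completed by Mir487b, Mirlet7d and Mir433, held 51.5% ± 2.12 of counts (SD, n = 2). The share was 49.97% in replicate 1 (95% Wilson interval 49.9 to 50.02) and 52.97% in replicate 2 (52.9 to 53.03). Such intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Of all reads in the libraries, counted or not, these genes took 16.2%. The ranking covers assigned counts, and reads that mapped to several places, which were given to no gene, could change it.

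Genes ranked 11 to 20 ranged from 18093 ± 8413 CPM for Mir744 to 11048 ± 1409 CPM for Mir652. Between them came Mir149, Mirlet7e, Mir99b, Mir23b, Mir100, Mir382, Mir132 and Mir191. Mirlet7e at 16021 ± 109 CPM and Mir191 at 11185 ± 1915 CPM each overlap a second miRNA gene on the other strand. Both were at 0 in the count column that ignored strand. Mir487b and Mir23b share a stretch of 20 nucleotides with another annotated miRNA gene, so their counts are uncertain. A total of 426 of the 2202 genes (19.3%) reached 2 CPM in both libraries, and 111 genes at 1000 CPM or more held 95.8% of counts. Of the 426 detected genes, 231 lay in introns and 76 in exons of a host gene on the same strand, and 119 were intergenic.

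In mm10, Mirlet7b (ENSMUSG00000065564.1) spans positions 85707319 to 85707403 of chromosome 15, in an exon of the non-coding gene Lncppara. Mir127 (ENSMUSG00000070076.2) lies at 109592846 to 109592915 of chromosome 12, outside annotated same-strand genes. Mir99a (ENSMUSG00000065530.1) lies at 77598936 to 77599000 of chromosome 16 in an intron of Mir99ahg. Mir139 (ENSMUSG00000065446.1) lies at 101475376 to 101475443 of chromosome 7. Mirlet7i (ENSMUSG00000065406.3) is intergenic at 122985640 to 122985724 of chromosome 10.

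The second comparison set 24 lists of miRNA genes, grouped by family, locus or cell type, against the other genes. Members of all lists together held 73.7% ± 1.00 of counts (SD, n = 2). The let-7 family had 13 of 14 members detected and held 22.4% ± 3.25 of counts, led by Mirlet7b, Mirlet7i and Mirlet7g. The list of miR-99, miR-100 and miR-125 genes, which often sit beside let-7 genes, held 11.2% ± 2.58, with Mir99b at 13399 ± 8571 CPM and Mir100 at 12223 ± 2888 CPM after Mir99a. The miR-181 family held 0.964% ± 0.146, with Mir181d at 3594 ± 492 CPM, Mir181b-2, which shares a stretch with another miRNA gene, at 2787 ± 655 CPM and Mir181c at 2416 ± 89.2 CPM. The neuron-enriched list had 22 of 26 members detected and held 6.18% ± 0.973, led by Mir149 at 17231 ± 4255 CPM, Mir132 at 11607 ± 8004 CPM and Mir330 at 6020 ± 564 CPM.

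These 4 lists lay above the other genes with a count in a two-sided permutation test of median log2(CPM + 0.5) across genes. The difference of medians was 8.48 for let-7 (adjusted p = 0.000307), 11.12 for the miR-99, miR-100 and miR-125 list (adjusted p = 0.00023), 8.07 for miR-181 (adjusted p = 0.0248) and 6.80 for neuron-enriched (adjusted p = 0.000518). Imprinted lists, described next, brought the passing lists to 6 of the 23 tested, all of them higher, and genes are not independent replicates. Among detected genes alone the miR-181 difference was 3.98 (adjusted p = 0.138 by permutation). The other differences were smaller there too, at 4.69 for let-7, 7.05 for the miR-99, miR-100 and miR-125 list and 4.29 for neuron-enriched. Their adjusted p-values in that permutation test were 0.0144, 0.00133 and 0.00361. Of the 26 neuron-enriched members, 16 share a 20-nucleotide stretch with another miRNA gene. Among these, named after their values were seen, Mir124a-1 had 12 and 4 counts, Mir124a-2 had 5 and 1, and Mir124a-3 had 0 and 4 in replicates 1 and 2.

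**Figure D1:**
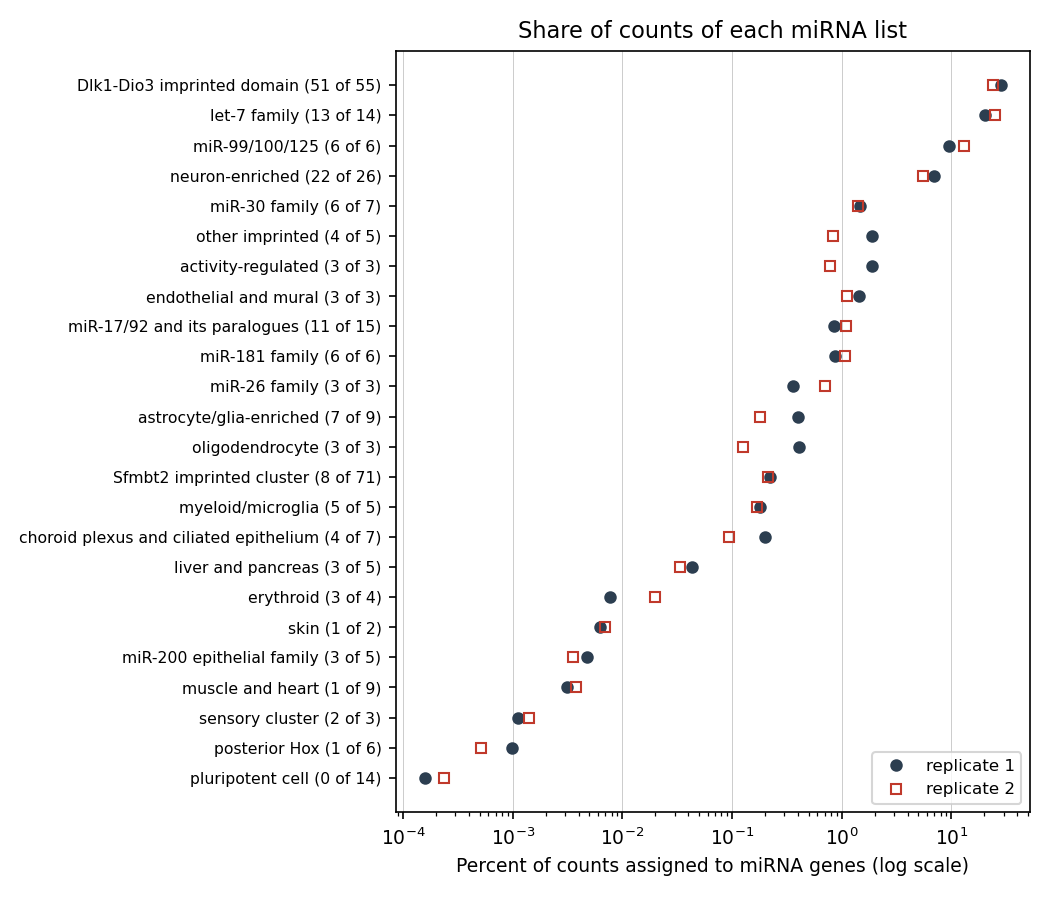
Percent of counts on miRNA genes held by each list (x axis, log scale), with filled circles for replicate 1 and open squares for replicate 2. The numbers beside each list name are its detected and listed members. The Dlk1-Dio3 domain, at 28.3% and 24.1%, and the let-7 family, at 20.1% and 24.7%, lie at the top, and the pluripotent cell list has no detected member.

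Imprinted loci made up a large part of the counts assigned to miRNA genes. Multimapping reads, which were given to no gene, are not in these shares and could change them. Of the 55 listed members of the Dlk1-Dio3 domain, 7 share a 20-nucleotide stretch with another miRNA gene. The Dlk1-Dio3 domain, whose miRNAs are expressed from the maternal chromosome, held 26.2% ± 2.95 of counts (SD, n = 2). Its 51 detected members, of 55 listed, spread over 184 kb of chromosome 12 from 109563692 to 109747960. Mir127, Mir770, which overlaps Meg3, and Mir487b at 27493 ± 16433 CPM led the domain, and Mir433 and Mir382 were at 19842 ± 2013 and 11680 ± 435 CPM. The median of the domain lay 7.99 log2 units above the other genes with a count (adjusted p = 0.00023, with the unadjusted p = 1e-05 the smallest that the permutations can give). Among detected genes alone the difference was 4.11 (adjusted p = 0.00038 by permutation). The list of other imprinted genes held 1.36% ± 0.745, from Mir298 at 9540 ± 8971 CPM, Mir296 at 2452 ± 1290 CPM and Mir335, in an intron of Mest, at 1491 ± 280 CPM. Its difference was 8.22 (adjusted p = 0.0467 by permutation), which did not pass in replicate 1 alone (7.95, adjusted p = 0.059) or among detected genes (4.48, adjusted p = 0.138).

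The miRNA cluster in an intron of Sfmbt2 on chromosome 2 had 8 of 71 members detected and held 0.218% ± 0.00758 of counts. Mir467d was highest at 1021 ± 235 CPM, then Mir669c at 414 ± 148 CPM and Mir467e at 313 ± 35 CPM. Of the 71 members, 70 share a 20-nucleotide stretch with another miRNA gene. The list did not pass the permutation test (adjusted p = 0.129).

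**Figure D2:**
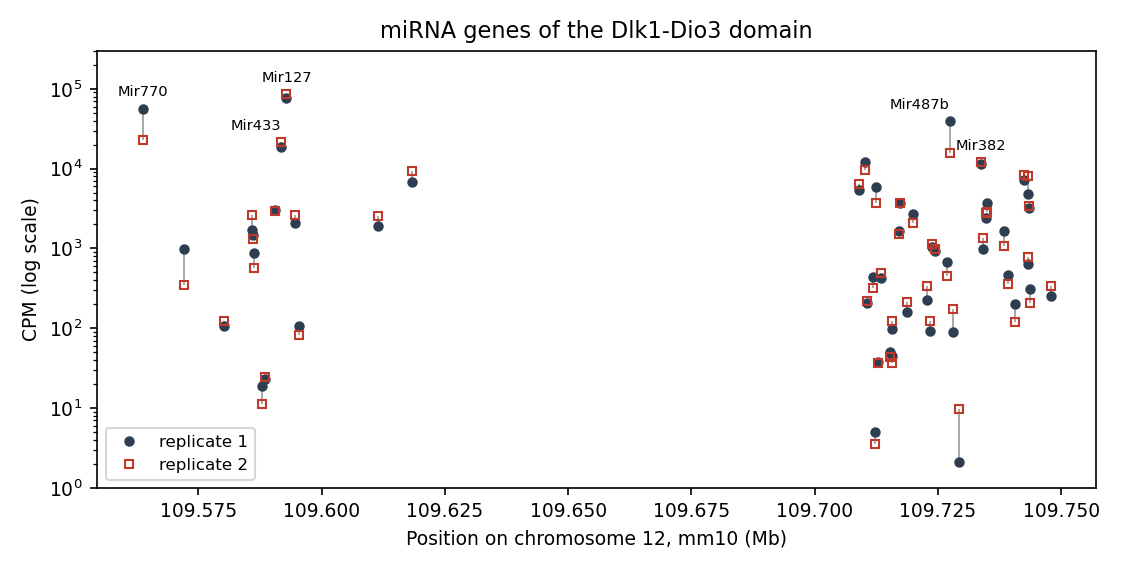
CPM (y axis, log scale) of the 51 detected miRNA genes of the Dlk1-Dio3 domain against their position on chromosome 12 of mm10 in Mb, with circles for replicate 1, squares for replicate 2 and a line joining the values of a gene. Mir127 is highest at 80675 CPM on average, and Mir770 and Mir487b stand lower in replicate 2.

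Lists of other families and of activity-regulated genes held from 0.530% to 1.42% of counts. The miR-30 family held 1.42% ± 0.0456 of counts, with Mir30d at 8676 ± 738 CPM, Mir30a at 3208 ± 152 CPM and Mir30e at 2004 ± 78.5 CPM. The genes of miR-17/92 and its paralogues held 0.974% ± 0.173, led by Mir93 at 4490 ± 982 CPM, Mir17 at 2205 ± 137 CPM and Mir92-1, which shares a stretch with another miRNA gene, at 1494 ± 223 CPM. The miR-26 family held 0.530% ± 0.237, nearly all of it from Mir26b at 5202 ± 2454 CPM, while Mir26a-1 and Mir26a-2, which each share a stretch with another miRNA gene, were at 69.1 ± 70.03 and 30.1 ± 13.8 CPM. The activity-regulated list, of miRNAs induced by neuronal firing, held 1.32% ± 0.777, from Mir132, Mir134 at 1157 ± 248 CPM and Mir212 at 481 ± 13.8 CPM. Adjusted p-values of the permutation test were 0.052 for miR-30, 0.1002 for miR-17/92, 0.323 for miR-26 and 0.116 for the activity-regulated list. The miR-30 family passed in replicate 2 alone (adjusted p = 0.0455) and without genes that share a stretch, an alternative chosen after seeing the data (adjusted p = 0.0204).

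Lists of other brain and vascular cell types held from 0.146% to 1.27% of counts. The endothelial and mural list held 1.27% ± 0.23, from Mir126a in Egfl7 at 9568 ± 2460 CPM, Mir143 at 2951 ± 166 CPM and Mir145a at 185 ± 8.46 CPM. The astrocyte and glia-enriched list held 0.291% ± 0.156, led by Mir29a at 1268 ± 19.8 CPM, Mir21a at 892 ± 790 CPM and Mir31 at 545 ± 697 CPM. The oligodendrocyte list held 0.265% ± 0.199, from Mir219a-2, a driver of oligodendrocyte maturation, at 1878 ± 1606 CPM, Mir338 at 757 ± 384 CPM and Mir219a-1 at 18.02 ± 1.63 CPM. Mir219a-2 and Mir219a-1 share a 20-nucleotide stretch with another miRNA gene, so their counts are uncertain. The myeloid and microglia list held 0.174% ± 0.00599, from Mir150 at 1014 ± 46.3 CPM, Mir146, uncertain for the same reason, at 622 ± 109 CPM and Mir142 at 50.2 ± 6.2 CPM for its 3 highest members. The choroid plexus and ciliated epithelium list held 0.146% ± 0.0742, from Mir204 in an intron of Trpm3 at 662 ± 114 CPM, Mir34c at 483 ± 529 CPM and Mir449a at 294 ± 97.05 CPM.

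None of these 5 lists passed the permutation test (adjusted p = 0.052 for endothelial and mural, 0.238, 0.129, 0.274 and 0.225 for the others in the order given). In replicate 2 alone the endothelial and mural list passed (adjusted p = 0.0455), as it did without genes that share a stretch (adjusted p = 0.0482). In the column that ignored strand, the endothelial and mural share was 0.333% and the oligodendrocyte share 2.08e-05%. That column gives no gene to reads where miRNA genes overlap on opposite strands, as Mir126a does with Mir126b and Mir219a-2 with Mir219b. Mir338 and Mir219a-1 were at 0 in it. These falls are thus losses of reads in counting and do not measure abundance.

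Lists of cell types of other organs and of blood took small shares. The liver and pancreas list held 0.0383% ± 0.0064, from Mir375 at 340 ± 54.4 CPM, Mir122 at 25.2 ± 6.5 CPM and Mir217 at 13.6 ± 13.6 CPM. The erythroid list held 0.0136% ± 0.00844, with Mir451a at 102 ± 85.2 CPM, Mir486 at 18.7 ± 8.2 CPM and Mir144 at 12.9 ± 5.56 CPM. Its share was 0.00137% in the column that ignored strand, where Mir451a and Mir486 were at 0. The skin list held 0.00655% ± 0.000472, with Mir203 at 64.1 ± 5.66 CPM. The miR-200 epithelial family held 0.00412% ± 0.000845, from Mir200c at 17.3 ± 10.1 CPM, Mir429 at 14.6 ± 4.00 CPM and Mir200b at 7.58 ± 5.88 CPM. The muscle and heart list held 0.00343% ± 0.000458, with Mir206 at 31.5 ± 5.8 CPM as its 1 detected member of 9. Of the 9, 5 share a 20-nucleotide stretch with another miRNA gene and had 0 counts. Their reads may be among the multimapping ones, so the low share is uncertain. The sensory cluster, with Mir183 at 8.26 ± 0.497 CPM and Mir182 at 4.06 ± 2.01 CPM, held 0.00126% ± 0.000214, and the posterior Hox list, with Mir10a at 3.48 ± 1.04 CPM, held 0.000742% ± 0.00033. None of the 14 members of the pluripotent cell list was detected, and the list had 6 counts in each library, 0.000158% and 0.000235% of counts. Of the pluripotent cell members 4, and of the posterior Hox members 2, share such a stretch and are uncertain too. Adjusted p-values of the permutation test lay between 0.323 and 0.94 for the 7 of these 8 lists that were tested, and the skin list had too few members.

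The third comparison was of the 2 libraries. Across the 426 detected genes, log2(CPM + 0.5) of the libraries had a Spearman correlation of 0.970 (95% bootstrap interval 0.960 to 0.977) and a Pearson correlation of 0.977 (0.969 to 0.982), over genes, which are not independent replicates. The 10 highest genes of each library had 7 in common and the 100 highest had 91. A chi-square of the counts over genes was 264254 on 506 degrees of freedom, so the libraries differed by more than sampling noise, which does not tell separate samples from separate preparations. They were counted as 2 samples from their labels. Among 328 genes with a mean of 10 CPM or more, the median absolute log2 ratio was 0.42 and 47 genes were over 2-fold apart, 34 of them higher in replicate 1. The coefficient of variation between replicates beyond counting error was 0.377 (95% bootstrap interval over genes 0.336 to 0.420), from edgeR's common dispersion with 1 residual degree of freedom per gene. The median of DESeq2's estimates per gene was 0.172.

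In the exact binomial test, 264 of 507 genes differed between the libraries, 128 higher in replicate 1 and 136 higher in replicate 2. The test compares these libraries and not conditions. Mir31 was 19.7-fold higher in replicate 1, with 3936 counts there and 133 in replicate 2, and Mir34c was 7.82-fold higher with 3252 and 279 counts. Mir26a-1 (5.93-fold, adjusted p = 1.54e-50), Mir217 (5.37-fold, adjusted p = 2.22e-10) and Mir1247 (5.21-fold, adjusted p = 1.85e-29) were also higher in replicate 1 in the exact binomial test. Mir301, in an intron of Ska2, was 24.4-fold higher in replicate 2, with 87 counts in replicate 1 and 1461 in replicate 2. By the same exact test Mir153 was 4.22-fold higher in replicate 2 (adjusted p = 3.29e-46), the erythroid Mir451a 3.84-fold (adjusted p = 1.61e-53), Mir491 2.70-fold (adjusted p = 1.27e-28) and Mir148a 2.68-fold (adjusted p = 7.24e-15). With a negative binomial spread set to edgeR's common dispersion, estimated from the same libraries, 2 genes passed, Mir31 (adjusted p = 0.000398) and Mir301 (adjusted p = 0.000227), and 23 had an unadjusted p under 0.05.

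**Figure D3:**
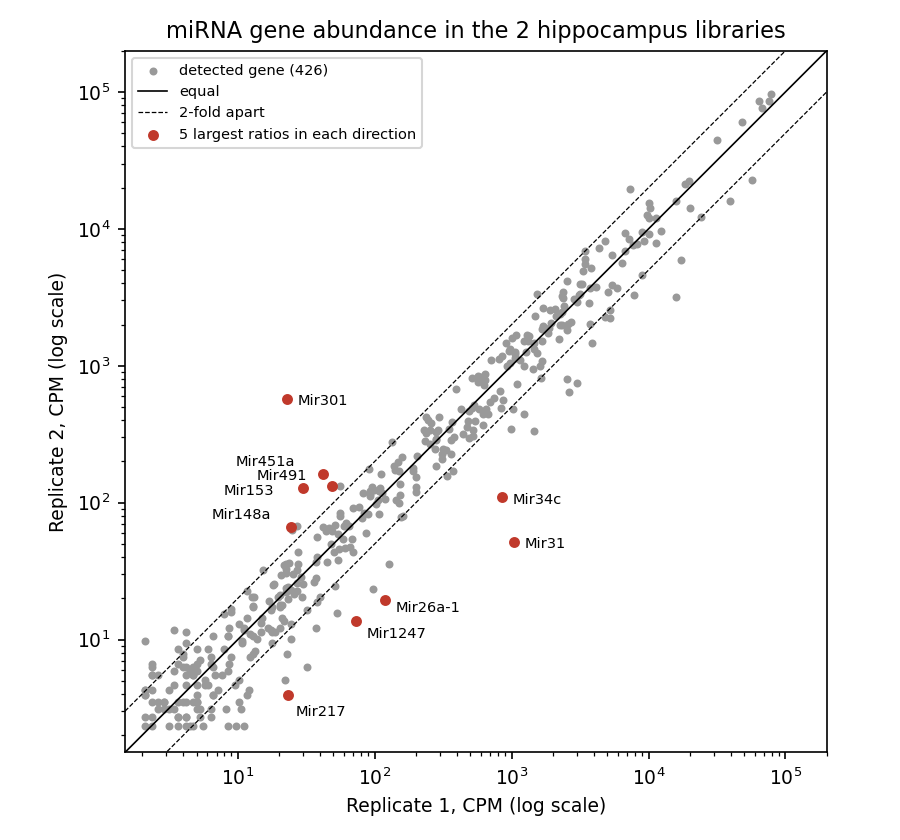
CPM of each of the 426 detected genes in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, with a solid line at equality and dashed lines at 2-fold differences. Red points are the 5 genes with the largest ratio in each direction, among genes with a mean of 10 CPM or more that passed the exact binomial test. Of these, Mir301 and Mir31 lie farthest from the line.

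Members of the fixed lists differed between the libraries in both directions in most lists. In the Dlk1-Dio3 domain 42 of 51 members differed, 18 higher in replicate 1 and 24 in replicate 2 (42 adjusted over the list alone). Mir770 was 2.503-fold and Mir487b 2.46-fold higher in replicate 1. Of the neuron-enriched genes 18 of 23 tested differed (18 adjusted over the list alone), 6 higher in replicate 1, among them Mir132 at 2.90-fold, and 12 higher in replicate 2. Of 13 tested let-7 members, 7 were higher in replicate 2 and 1 in replicate 1, 8 and 1 when adjusted over the list alone. Of 11 tested members of the miR-17/92 list, 7 were higher in replicate 2 and 0 in replicate 1. Of 6 tested in the miR-181 family, the numbers were 5 and 0 (6 and 0 when adjusted over the list alone). TMM-scaled totals and DESeq2 size factors moved the log2 ratios by only -0.01 and 0.02, too little to test these directions.

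Lists of other cell types went in different ways. For scale, 52.1% of all tested genes differed. In the oligodendrocyte list 2 of 3 tested members were higher in replicate 1 and 0 in replicate 2. These were Mir219a-2, uncertain for its shared stretch, by 4.06-fold and Mir338 by 2.12-fold. The list held 0.406% and 0.125% of counts in replicates 1 and 2. In the astrocyte and glia-enriched list 4 of 9 tested members were higher in replicate 1 and 0 in replicate 2, and the list held 0.401% and 0.181%. Mir21a was 4.35-fold and Mir31 19.7-fold higher in replicate 1. Mir29a, the most abundant member, was not past the threshold (exact binomial test, adjusted p = 0.438). In the choroid plexus and ciliated epithelium list 3 of 4 tested members were higher in replicate 1 and 0 in replicate 2, and the list held 0.198% and 0.0931%. Its Mir34c was at 857 and 109 CPM in replicates 1 and 2. The neighbouring Mir34b was at 14.8 and 13.3 CPM and not past the threshold (exact binomial test, adjusted p = 0.753). Counts adjusted over the list alone were 2, 4 and 3 for these lists. Of 5 tested members of the myeloid and microglia list, 2 were higher in each library. In the endothelial and mural list and the miR-200 family, with 3 tested members each, 1 was higher in each library. Mir200c was 2.34-fold higher in replicate 1 and Mir200b 3.12-fold higher in replicate 2. The activity-regulated list held 1.87% and 0.775%, with Mir132 higher in replicate 1, Mir134 1.36-fold higher in replicate 2 and Mir212 not past the threshold (exact binomial test, adjusted p = 0.386), and its median log2 ratio was -0.06 (percentile 47.3 among random lists). The other imprinted list held 1.89% and 0.838%, with Mir298 4.97-fold higher in replicate 1 and Mir296 2.19-fold higher in replicate 2. The erythroid list held 0.00767% and 0.0196%, with Mir486 1.86-fold higher in replicate 1 (exact binomial test, adjusted p = 0.00324) and Mir451a and Mir144 higher in replicate 2.

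Set against 10000 random lists matched on mean CPM, 3 of the 20 lists with at least 2 detected members had a median log2 ratio of replicate 2 over replicate 1 outside the central 95%. These were the erythroid list (0.87, percentile 98.8), the miR-17/92 list (0.40, percentile 98.1) and the Sfmbt2 cluster (-0.78, percentile 0.08). Members of the erythroid list and the Sfmbt2 cluster went both ways, with 4 genes of the cluster higher in replicate 1 and 3, Mir467d and Mir467e among them, higher in replicate 2. The oligodendrocyte median was -1.08 (percentile 4.77) and the astrocyte and glia-enriched median -0.42 (percentile 6.76). With a mean of at least 10 CPM the miR-17/92 list fell inside (percentile 95.2), and in the column that ignored strand the erythroid list had too few members for a value. The percentiles describe these 2 libraries. Some of 20 lists would fall outside a central 95% even if drawn at random. The random lists were also not matched on a common locus or shared sequence, which members of the Sfmbt2 cluster have.

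The last comparison was of genes that share a 20-nucleotide stretch with another annotated miRNA gene and genes that do not, because reads of repeated sequence can stay without a gene. Of the sharing genes, 85 of 1087 were detected (7.82%), against 341 of 1115 others (30.6%, Fisher's exact test, two-sided, p = 6.97e-44 across genes). That test takes genes as independent, which sharing genes are not, since 70 of them belong to the Sfmbt2 cluster alone. The p-value therefore overstates the evidence. Among genes with a count, the 132 sharing genes had a higher median log2(CPM + 0.5), 4.51, than the 626 others, 2.08 (difference 2.43, permutation test p = 0.00024). This difference did not pass in the permutation test with a stretch of 25 nucleotides (0.22, p = 0.754) or among detected genes (0.10, p = 0.877). In each library about as many reads mapped to several places as were assigned to miRNA genes, 95.7 per 100 assigned in replicate 1 and 106 in replicate 2. Of all reads, 27.5% and 35.3% were assigned, 4.85% and 6.51% lay outside miRNA genes, and 41.3% and 20.7% did not map.

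**Figure D4:**
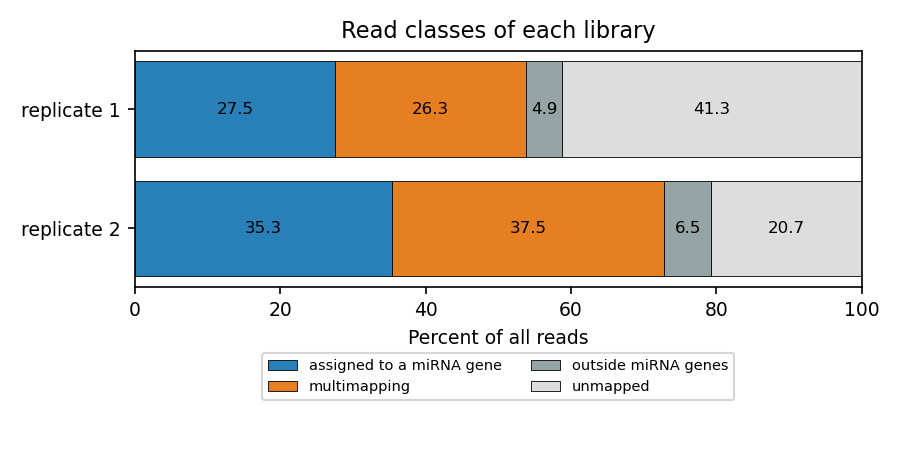
Percent of all reads (x axis) in each read class, as stacked bars from 0 for replicate 1 and replicate 2. Multimapping reads made up 26.3% and 37.5%, and unmapped reads 41.3% and 20.7%.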

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

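The tests on the opposite strand were chosen after the result was seen, and so was the placing of let-7j and let-7k outside the miR-7 family. Counts on the opposite strand of miRNA genes, in a column that the comparisons did not use, made up 5.43% of stranded counts in replicate 1 and 5.65% in replicate 2. In Mir126b, which overlaps Mir126a on the other strand, there were 42899 and 19999 such counts and 0 on its own strand. Over both libraries 99.9% of the opposite-strand counts were in genes that overlap a miRNA gene on the other strand. Those of Gm25927, 60491 and 41131, equalled the own-strand counts of Mirlet7e, which it overlaps. Those of Gm24083, 37298 and 32038, equalled the own-strand counts of Mir191, which it overlaps. Equal counts are what reads of the overlapping gene, counted under both genes, would give, and this is the candidate explanation. Genes without such an overlap held 136 and 71 opposite-strand counts. No biological explanation was tested, since the labels give 1 group.

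Multimapping reads, which the comparisons did not use, made up 26.3% of all reads in replicate 1 and 37.5% in replicate 2. In the let-7 family, described after its values were seen, the 6 genes that share a 20-nucleotide stretch with another miRNA gene were at 84.05 to 2760 CPM, whereas Mirlet7b, Mirlet7d, Mirlet7e, Mirlet7g and Mirlet7i were at 16021 to 87109 CPM. All 8 genes without a shared stretch, with Mir98 and the rare Mir7j and Mir7k, differed from the 6 by 5.25 log2 units in median, sharing genes lower (two-sided exact permutation p = 0.0786). If reads of repeated sequence were left uncounted, sharing genes should be lower in other families too. In 13 families the median difference was -3.31 log2 units, with sharing genes lower in 11 (exact permutation of signs, p = 0.0703), and -3.18 with let-7j and let-7k counted as miR-7 genes. The miR-344 and miR-378 families went the other way, by 2.32 and 5.58, and the p-value leaves open whether uncounted reads may account for the low values. Only families that hold both kinds of gene could enter this test. Families whose members all share a stretch, such as the Mir124a genes, were therefore left out, and the test says nothing of their losses. No biological explanation was tested.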

How the results depend on the processing

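Leaving out genes that share a 20-nucleotide stretch, or the gene with the most opposite-strand counts, were alternatives chosen after seeing the data. Of 434 alternative values, 353 kept their side of the threshold or stayed within the spread. Another 206, of a single library against a mean of 2, are not counted, since they cannot leave 1 SD. In 12 cases a difference of list medians that passed under neither setting changed sign, and the cause was not tested. The median log2 ratio of the endothelial and mural list, inside the random range, went from -0.09 to 0.12 without strand. The differences of list medians that changed sign among detected genes were myeloid and microglia -0.75, erythroid -2.24, miR-200 -2.55, liver and pancreas -1.75 and miR-26 -0.80. In replicates 1 and 2 alone miR-200 was -0.42 and 1.15, liver and pancreas 2.01 and -0.12, and the sensory cluster -0.74 and 0.32. The sensory cluster was 3.11 and posterior Hox 0.67 with genes at 0 counts included, and the sensory cluster 0.0455 in the column that ignored strand and 0.0456 without genes sharing a stretch. Replicates 1 and 2 alone gave 471 and 453 detected genes, against 426 in both, and 5 and 8 passing lists, against 6. With the column that ignored strand, the share of the 10 most abundant genes was 54.7%, and over all reads it was 16.2%, since the denominator then holds reads without a gene. Without Mirlet7b, the most abundant gene, the opposite-strand share was 6.04% and the share of all lists 71.2%, and without Gm25927, which overlaps Mirlet7e, the opposite-strand share was 4.09%. The Spearman correlation over all genes with a count was 0.937, where low counts enter. With a negative binomial spread 2 genes differed, against 264, since that spread includes the difference between replicates. Counts under the other settings were 235 to 268. DESeq2's median estimate of the coefficient of variation was 0.172, and the cause was not tested. With genes at 0 counts included, 18 lists passed, because most other genes were then at 0. The difference of sharing and other genes was 0.22 at 25 nucleotides and 0.10 among detected genes, and the cause was not tested. For single lists, 39 of 50 alternative shares stayed within 1 SD, and of 151 alternative abundance values 3 lost and 16 gained the threshold. In replicate 1, 1 count was worth 0.264 CPM and in replicate 2 0.391 CPM, which limits values near 2 CPM. No paired analysis was possible because the series has 1 group.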

Other observations

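Tests of library scaling, shared primary transcripts and sequence-dependent capture were chosen after the result was seen. By chromosome, chromosome 12 held 27.1% ± 2.99 of counts (SD, n = 2) with 65 of 146 annotated genes detected. Chromosome 15 followed with 10.7% ± 1.24, chromosome 7 with 8.5% ± 0.63 and chromosome 16 with 8.13% ± 1.53. Chromosome X held 3.88% ± 0.236 with 40 of 142 genes detected, and none of the 6 annotated genes of chromosome Y was detected.

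The difference between the libraries exceeded counting error in each of the 4 ranges of abundance compared. The median absolute log2 ratio was 0.50 for genes at 2 to 10 CPM, where counting alone would give 0.39, and 0.35 for genes at 1000 CPM or more, where counting alone would give 0.01. Of the 111 genes at 1000 CPM or more, 15 were over 2-fold apart.

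Technical explanations were weighed for the 264 genes that differed beyond counting error. Library scaling is argued against, since 17 single factors from 0.25 to 4 left at least 52.1% of tested genes different, and so is hairpin GC content, whose Spearman correlation with the log2 ratio across 328 genes was -0.129 (95% bootstrap interval -0.231 to -0.0201). Shared primary transcripts stay open. Same-strand neighbours within 10 kb differed by 0.754 of the median difference after shuffling (362 pairs, permutation p = 0.0257). The bootstrap interval of this ratio over 37 loci was 0.715 to 1.25, which includes equality. Outside chromosome 12 the ratio was 0.954 (68 pairs, bootstrap interval over 34 loci 0.416 to 1.58). Sequence-dependent capture stays open too. Genes that share 15 nucleotides and are not such neighbours differed by 0.644 of that after shuffling (63 pairs, permutation p = 0.0213). The bootstrap interval of this ratio over 30 loci was 0.486 to 1.19, which includes equality. Without let-7 genes the ratio was 0.797 (permutation p = 0.268). Some pairs, such as Mir467c and Mir467d, lie in the same Sfmbt2 cluster, so the test does not fully separate shared sequence from a shared primary transcript. The labels number the males of the 2 samples differently but give both the same donor identifier, and a difference between animals was not tested.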
